A study of Homo sapiens with 9 samples.

How the data were processed

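The data are RNA-seq read counts for 9 human glioma samples. Per the labels' protocols, messenger RNA was purified by its poly-A tail, made into indexed libraries and sequenced for 50 bp on an Illumina HiSeq, and reads were aligned to hg19 with TopHat2; the submitters' processing notes also name STAR. Versions, the counting program, the gene annotation and any strand setting were not given in the sources used here. The deposited table holds raw counts per Entrez gene ID, with no normalization, as its whole numbers and unequal column sums show. Because the counting is not described, reads of overlapping, antisense or near-identical genes may be split between them, and values of such genes are uncertain.

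Of 27380 IDs, 27252 were matched to gene names in an NCBI RefSeq gene table (GRCh38 assembly, used for names and gene classes alone) and 128 were not. IDs without a match were left out of tests, since their chromosome is unknown, as were 116 genes that report a person's sex (XIST, TSIX and Y-linked genes), leaving 27136. Coordinates are those of the GENCODE annotation lifted to hg19 (GRCh37), matched by gene symbol. Totals per library ran from 9 to 18.6 M reads, under the depth the study's design text aims at; deposited counts cover assigned reads alone. Precision is set by the number of libraries: 6 treated and 3 control, with 2 per dose.

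Groups and doses come from the sample titles. Counts were normalized by TMM and tested with edgeR 4.0.16 (quasi-likelihood F-test, filterByExpr, Benjamini-Hochberg threshold 0.05) in R 4.3.3. Treated libraries were compared with controls in a 2-group fit over all 9 libraries. Each dose against control, and any difference among the 3 doses, came from a 4-group fit over all 9 libraries, in which groups share the estimate of spread. The trend with dose used log2 dose in the 6 treated libraries. Comparisons of doses with control share the same 3 control libraries, so no overlap between their calls is reported. CPM values use the TMM library sizes of the 2-group fit.

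Lists of genes for pathways, tumor states and cell types, 29 in all, were fixed before the data were examined and tested with camera (limma 3.58.1) on log2 CPM with a preset inter-gene correlation of 0.01, for lists with at least 5 measured members. The test was repeated with an estimated correlation and with fry. Means, medians and scores of lists are on the log2 CPM scale, while counts of higher and lower members use edgeR fold changes; these can differ in sign where a few libraries hold most of the reads, as for proliferation genes in treated against control. Shares of counts and list scores were compared with exact permutation tests over the 84 ways to pick 3 of 9 libraries.

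Genes were named by a rule fixed in advance. For treated against control it took up to 10 genes per direction past the threshold and without overlap between the arms, or else the 5 of smallest p per direction; for each dose and the trend, up to 4 per direction past the threshold, or else the 2 of smallest p; for the difference among doses the 4 of smallest p; and genes chosen in advance (among them CYP19A1, ESR1, ESR2, GPER1, HSD17B1, STS, MKI67, BRCA2 and MGMT). A mean of at least 1 CPM was required, and pseudogenes were skipped. For each list described, the 3 members of smallest p were eligible. Results on some genes that the rule or the tests reached are not reported here. STAR, EGFR, CDKN2A, CDKN2B, LANCL2, CHCHD2, MTAP, SNAP25, MAP2, MEG3, APOE, GSN and NEAT1 fall outside the rule, as do the values of MKI67 and CYP19A1 at 10 mg and of APOD and PTGDS at 10 mg; they were chosen after their values were seen.

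Scripts were tested on simulated counts with the depths and spread of these libraries, 200 genes being changed by known folds. For treated against control (19825 genes) edgeR recovered 0% of genes changed 2-fold, 30% at 4-fold, 74% at 8-fold and 82% at 16-fold, with 5 false calls among 98; DESeq2 made 84 false calls among 213. For 2.5 mg against control (20423 genes) edgeR recovered 0%, 10%, 40% and 66%, with 0 false calls among 58; for 5 mg (20423 genes) 0%, 2%, 46% and 72%, with 3 among 63; for 10 mg (20437 genes) 0%, 10%, 48% and 74%, with 2 among 68. For the trend (19119 genes) it called 0 genes, and DESeq2 made 102 false calls among 192. A simulated shift of the cholesterol list was called in both comparisons, with 0 of the 28 other lists. Genes were simulated independently of each other, so this check cannot show false list calls that arise from correlated genes.

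Alternatives fixed in advance were DESeq2 size factors, no filter, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, a 4-group model for the pooled comparison, fits of only the 5 samples compared, and leaving out each library in turn. Fits of protein-coding genes alone and without 5 mg replicate 1 and 10 mg replicate 1 together were added after seeing the data. No library duplicated another. Figures were drawn with matplotlib 3.10.9.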

Results

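Gene expression was measured by RNA-seq in 9 tumor samples of recurrent high-grade glioma, a group of fast-growing brain tumors. Letrozole blocks aromatase, the enzyme encoded by CYP19A1 that makes estrogens from androgens. Of the 9 libraries, 6 came from letrozole-treated tumors in 3 dose groups (2.5, 5 and 10 mg, 2 libraries each) and 3 were labelled as controls. The other therapy each tumor received, the tumor subtype and how the samples were taken were not given in the sources used here. Nothing in the labels says that libraries of a group came from separate donors, so p-values measure the spread between these libraries. Dose labels did not group the most alike libraries. The 2 libraries of a dose had Spearman correlations of 0.896 (2.5 mg), 0.889 (5 mg) and 0.897 (10 mg). Across doses, 5 mg and 10 mg replicate 1 reached 0.969 and 2.5 mg and 10 mg replicate 2 reached 0.931, while other pairs went as low as 0.823. The controls correlated with each other at 0.921 to 0.957. Counts covered 27380 genes. Totals ran from 9 to 12 M reads in the controls (10.3 ± 1.57, SD, n = 3) and from 11.8 to 18.6 M in the treated libraries (15.2 ± 2.46, SD, n = 6; exact permutation test, two-sided, p = 0.0476).

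The composition of the libraries differed between the arms. Long non-coding RNA (lncRNA) took 5.04% ± 0.757 (SD, n = 6) of the counts in treated libraries and 8.51% ± 0.526 (SD, n = 3) in controls. Pseudogenes took 0.995% ± 0.109 against 1.58% ± 0.215, and small nuclear RNA (snRNA), the RNA of the splicing machinery, 0.193% ± 0.117 against 0.654% ± 0.251. Protein-coding genes took 93.0% ± 0.849 against 88.5% ± 0.198. In each of these 4 classes the arms did not overlap (exact permutation test, two-sided, p = 0.0238, the smallest that 6 against 3 libraries can give; Benjamini-Hochberg p = 0.0536 over 9 measures). The median log2 fold change, treated over control, was -0.64 over 2804 lncRNA genes and 0.24 over 16204 protein-coding genes. At unadjusted p under 0.05, 1004 lncRNA genes were lower and 32 higher, while 1324 protein-coding genes were lower and 2284 higher.

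**Figure D1:**
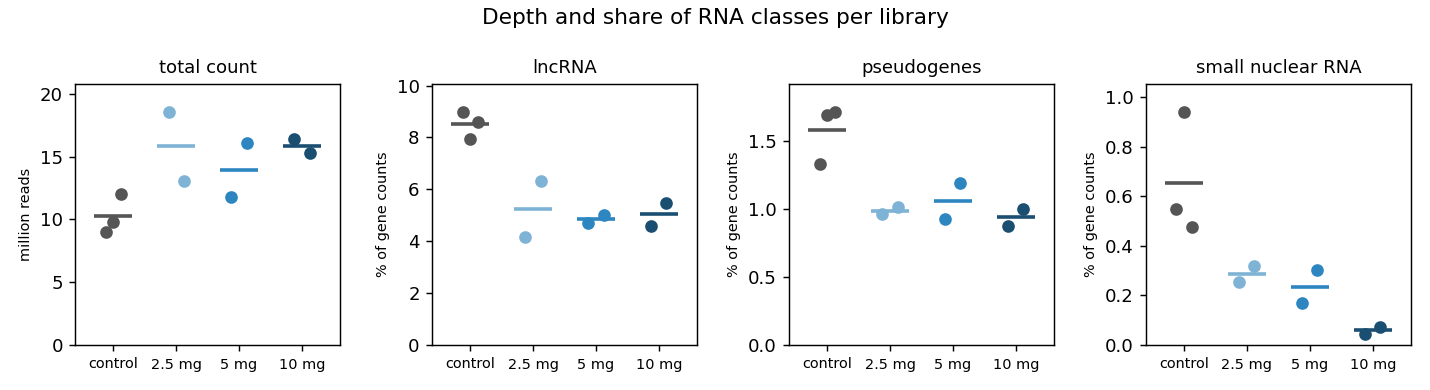
Total gene counts in M reads and the percent of counts on lncRNA, pseudogenes and snRNA, by group; each point is 1 library and each line a group mean. The lncRNA share lies between 4.17% and 6.31% in the treated libraries and between 7.95% and 8.99% in the controls.

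The first comparison asked how letrozole-treated tumors differed from controls. Genes of oxidative phosphorylation, the mitochondrial respiratory chain encoded in the nucleus, rose as a group: all 38 measured members had a higher level in treated libraries, with a median 1.92-fold difference. Of these members, 29 passed adjusted over the list alone and 0 adjusted over all genes. SDHB, a subunit of complex II, averaged 25.7 CPM ± 4.84 (SD, n = 6) in treated and 9.75 ± 2.19 (SD, n = 3) in control libraries, 2.63-fold apart. COX4I1, of complex IV, was 2.52-fold and UQCRC2, of complex III, 2.35-fold apart. The list's score exceeded every control in 6 of 6 treated libraries, by 0.585 to 1.22 log2 units over the control mean (exact permutation test, two-sided, p = 0.0238). It passed the set test (camera adjusted p = 1.89e-15; adjusted p = 0.86 with an estimated correlation), and it was the 1 list that moved on balance in a single direction by the rotation test fry (adjusted p = 0.0184).

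Cytosolic ribosomal protein genes also rose as a group, by a median of 1.90-fold, with 58 of 58 members higher, 0 of them adjusted over the list alone (camera adjusted p = 1.57e-11; adjusted p = 0.9 with an estimated correlation). RPS13 was 2.40-fold, RPLP2 2.10-fold and RPS6 4.58-fold higher in the fit, none past adjusted p 0.05. RPS6 is also 1 of the 15 measured neighbors of KLHL9 on chromosome 9, and its level in 2.5 mg replicate 1 stood far above the rest, as did the score of the whole list there (2.44, against 0.433 to 0.773 in the other treated libraries). Protein-coding genes as a class also took a larger share of the treated libraries. Fitted on protein-coding genes alone, the mean log2 differences were 0.79 for ribosomal proteins (camera adjusted p = 8.73e-10) and 0.81 for oxidative phosphorylation (1.11e-13). With all gene types they were 0.90 and 0.92. Such a fit removes the other gene types and rescales the libraries. It cannot show whether RNA preparation shifted some protein-coding genes against others. For these lists too, the labels do not separate preparation from treatment. Cholesterol synthesis genes rose by a median of 1.57-fold. The list's score was -0.058 in 2.5 mg replicate 2, below every control, and the arms overlapped (exact permutation test, two-sided, p = 0.0952). Here 22 of 25 members were higher, 6 of them adjusted over the list alone, as was 1 of the 3 lower members (camera adjusted p = 0.000361; adjusted p = 0.9 with an estimated correlation). The leading members were NSDHL (2.69-fold), STARD4 (2.45-fold) and DHCR7 (3.58-fold), the last enzyme step to cholesterol.

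**Figure D2:**
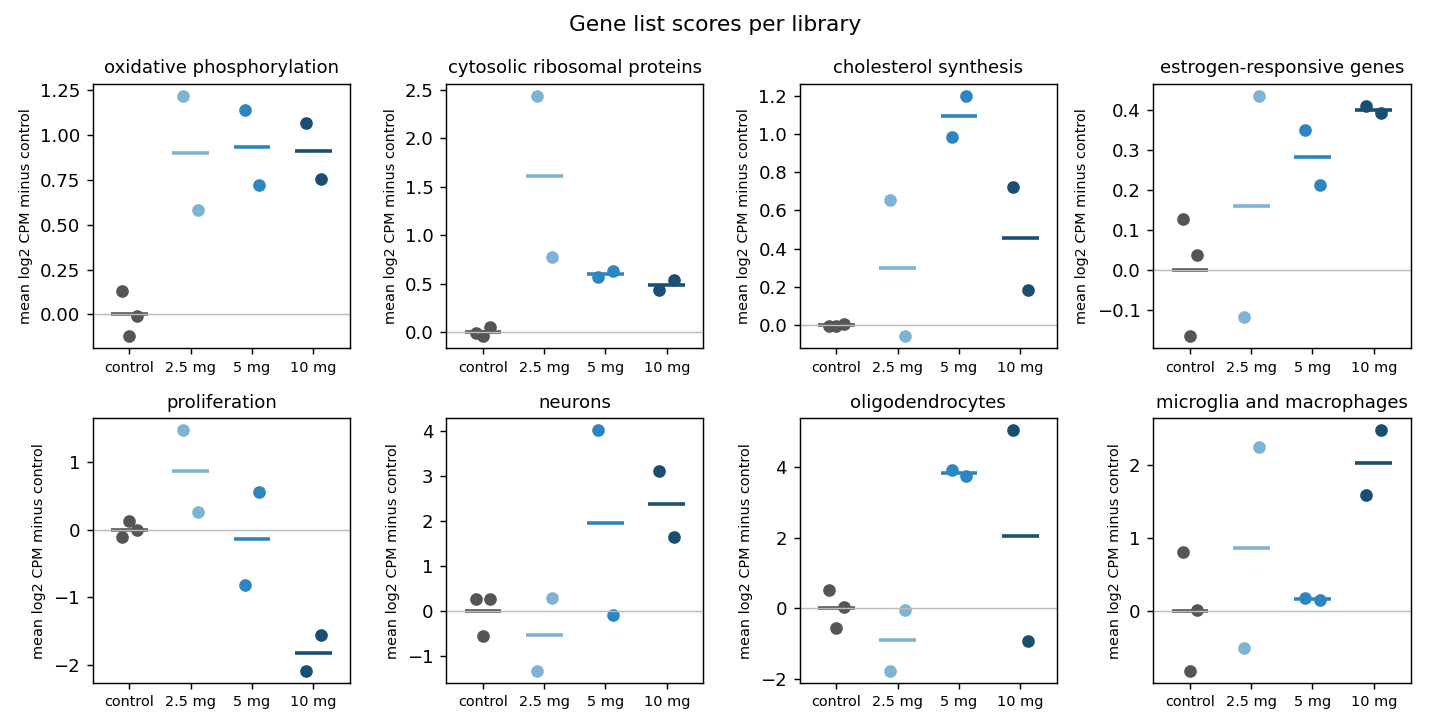
Mean log2 CPM of the members of 8 gene lists, minus the mean of the 3 control libraries, by group; each point is 1 library and each line a group mean. The oxidative phosphorylation score lies between 0.585 and 1.22 in the 6 treated libraries, and the proliferation score falls to -1.81 on average at 10 mg.

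Markers assigned to non-tumor cells were higher in treated libraries in several lists. The cell of origin was not measured, and 9 of the 22 measured pericyte and fibroblast genes are also in another list. Microglia and macrophage markers were higher in 33 of 33 genes (median 2.08-fold, camera adjusted p = 0.00155) and pericyte and fibroblast markers in 21 of 22 (median 2.27-fold, adjusted p = 0.00155). Endothelial markers were higher in 22 of 24 (median 1.53-fold, adjusted p = 0.00253). Neuron markers were higher in 25 of 28 genes (median 2.72-fold, adjusted p = 0.00715) and oligodendrocyte markers in 21 of 21 (median 3.42-fold, adjusted p = 0.00752). Each of these 5 calls was lost when the correlation was estimated (adjusted p = 0.9 with an estimated correlation for each), and adjusted over the list alone 1 pericyte gene, RGS5 (2.57-fold), passed and 0 of the other 4 lists. The scores of treated and control libraries overlapped for microglia (exact permutation test, two-sided, p = 0.262; 2.5 mg replicate 1 at -0.514), pericytes (p = 0.119), endothelial cells (p = 0.0476), neurons (p = 0.357) and oligodendrocytes (p = 0.452). The neuron scores were highest in 5 mg replicate 1 and 10 mg replicate 1 (4.02 and 3.12), which stood apart from the other libraries. Oligodendrocyte scores were high in these (3.9 and 5.02) and in 5 mg replicate 2 (3.73). Without 5 mg and 10 mg replicate 1, the mean log2 difference was 0.14 (adjusted p = 0.625) for neurons and 0.25 (adjusted p = 0.41) for oligodendrocytes.

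Interferon response genes fell as a group, by a median of 1.73-fold, with 32 of 44 members lower and 0 adjusted over the list alone (camera adjusted p = 0.00324; adjusted p = 0.9 with an estimated correlation). IRF1, a transcription factor induced by interferon, averaged 58.2 CPM ± 15.2 (SD, n = 6) against 109 ± 12.2 (SD, n = 3). The list's score was 1.2 in 10 mg replicate 2, above every control, and -1.83 to -0.49 in the other 5 treated libraries (exact permutation test, two-sided, p = 0.31). Without 5 mg and 10 mg replicate 1 the list no longer passed (mean -0.26, adjusted p = 0.281). Hypoxia response (24 of 33 higher, adjusted p = 0.0233), extracellular matrix (37 of 38 higher, adjusted p = 0.0289) and p53 target genes (22 of 28 higher, adjusted p = 0.0291) also passed, each with adjusted p = 0.9 with an estimated correlation. By exact permutation of the scores, p was 0.429, 0.476 and 0.143. With protein-coding genes alone these 3 lists did not pass (adjusted p = 0.119, 0.111 and 0.151), with mean log2 differences of 0.31, 0.76 and 0.35 against 0.41, 0.86 and 0.46 with all gene types, and the other 9 of the 12 did. Without 5 mg and 10 mg replicate 1 together all 3 passed, with means of 0.41 (adjusted p = 0.0166), 1.71 (7.55e-08) and 0.61 (0.00127). Adjusted over the list alone, 1 p53 target passed, PLK2 (2.90-fold), and 0 members of the other 2 lists. In all, 12 of 29 lists passed, 11 higher and 1 lower, 0 of them with an estimated correlation.

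Leaving out each library in turn, 6 of the 12 lists passed every time (oxidative phosphorylation, ribosomal proteins, cholesterol synthesis, microglia, pericytes and interferon response). Their sizes still moved. The mean log2 difference fell as low as 0.587 for ribosomal proteins (0.897 with all libraries) and 0.664 for microglia (1.02 with all libraries). Endothelial markers did not pass without control replicate 3 (adjusted p = 0.0588), neurons without 5 mg replicate 1 (adjusted p = 0.0675) or oligodendrocytes without 5 mg replicate 2 (adjusted p = 0.0792). Hypoxia was lost without 2.5 mg replicate 2, control replicate 2 or control replicate 3 (highest adjusted p = 0.283). The matrix and p53 lists were lost without either 2.5 mg replicate, 10 mg replicate 2, control replicate 2 or control replicate 3 (highest adjusted p = 0.381 and 0.163).

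Among genes of estrogen synthesis and reception, HSD17B12 (2.47-fold higher) and HSD17B4 (2.01-fold higher) and, lower in treated tumors, SULT2A1 (2.04-fold), ESR2 (1.95-fold) and STAR (log2 fold change -0.85) passed adjusted over the list alone. None passed adjusted over all genes, and the list as a whole did not move in 1 direction (10 of 22 higher, camera adjusted p = 0.555), although fry found changes in either direction (adjusted p = 0.00427). Falls approaching this size ran through a whole RNA class: the median log2 fold change was -0.64 over lncRNA genes, though 0.24 over protein-coding genes. Whether the 3 lower genes moved with that shift was not tested. ESR2, which encodes estrogen receptor beta, averaged 11.3 CPM ± 3.34 (SD, n = 6) in treated and 22.2 ± 4.91 (SD, n = 3) in control libraries. CYP19A1, the target of letrozole, averaged 1.89 CPM ± 1.66 and 4.36 ± 0.847 (log2 fold change -1.20 ± 0.71 SE, edgeR adjusted p = 0.312). HSD17B1, which makes estradiol from estrone, averaged 0.616 CPM ± 0.360 and 2.09 ± 1.71 (log2 fold change -1.73 ± 0.63 SE, adjusted p = 0.143); the highest of the 3 controls was at 3.99 and the lowest at 0.684, and the log2 fold change ran from -2.37 to -0.81 over the alternatives, the smallest difference being without control replicate 1. ESR1, which encodes estrogen receptor alpha, differed by less than its error (log2 fold change -0.04 ± 0.45 SE, adjusted p = 0.962), as did GPER1 (-0.15 ± 0.34 SE, adjusted p = 0.803). The direction of ESR1 and GPER1 turned when single libraries were left out. STS had a log2 fold change of 0.62 ± 0.40 SE (adjusted p = 0.352). Estrogen-responsive genes were higher in 21 of 29 cases (camera adjusted p = 0.277), with 0 adjusted over the list alone.

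Gene by gene, 0 of 20157 genes passed adjusted p 0.05 with edgeR (smallest 0.0719). At unadjusted p under 0.05, 4930 genes differed, 2331 higher and 2599 lower, where 1008 are expected by chance. DESeq2 called 3185 and limma-voom 1 (KLHL9). The genes of smallest p are therefore described as not past the threshold. KLHL9, an adaptor of a ubiquitin ligase (chromosome 9, 21329664 to 21335403, minus strand, hg19), averaged 80.8 CPM ± 13.4 (SD, n = 6) in treated and 8.82 ± 4.38 (SD, n = 3) in control libraries, with a log2 fold change of 3.20 ± 0.35 SE and adjusted p = 0.0719. KLHL9 passed with limma-voom (adjusted p = 0.0267), with protein-coding genes alone (0.0415) and without control replicate 1 (0.00355); its adjusted p over all alternatives ran from 1.19e-20 to 0.359. The 15 protein-coding genes measured within 3 Mb of it were all higher in treated libraries, with a median log2 fold change of 1.47. They include RRAGA, which codes for a GTPase of the amino acid sensing pathway and was itself among the 5 of smallest p (log2 fold change 1.47 ± 0.22 SE, adjusted p = 0.0897). SLC18B1, a polyamine transporter (1.87 ± 0.29 SE), and KCNT2, a potassium channel (2.45 ± 0.38 SE), were also among the genes of smallest p in this direction, each with adjusted p = 0.0897.

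On the lower side, FSIP2, a protein of the sperm fibrous sheath (chromosome 2, 186603531 to 186698017, plus strand), averaged 52.8 CPM ± 11.6 (SD, n = 6) in treated and 296 ± 118 (SD, n = 3) in control libraries (log2 fold change -2.49 ± 0.29 SE, adjusted p = 0.0719). FSIP2 passed with protein-coding genes alone (adjusted p = 0.0415) and without control replicate 1 (0.00918), within a range of 2.02e-09 to 0.359 over all alternatives. MC2R, the ACTH receptor, averaged 9.76 CPM ± 4.23 against 43.9 ± 8 (-2.17 ± 0.33 SE). CAPN10-DT, a divergent transcript (-1.40 ± 0.22 SE), MIR5191 (-2.24 ± 0.34 SE) and CSH2 (-4.28 ± 0.63 SE) followed, each with adjusted p = 0.0897. CSH2 belongs to a family of near-identical placental hormone genes, so its reads may be shared with copies. CAPN10-DT is non-coding, like the lncRNA class that was lower as a whole. Of the genes followed by plan, MKI67 (log2 fold change -0.06 ± 0.67 SE), BRCA2 (0.05 ± 0.65 SE) and MGMT (0.42 ± 0.65 SE) differed by less than their errors, with edgeR adjusted p from 0.713 to 0.968; the direction of MKI67 and BRCA2 turned when single libraries were left out, and MGMT ranged from 0.12 to 1.64 over the alternatives.

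**Figure D3:**
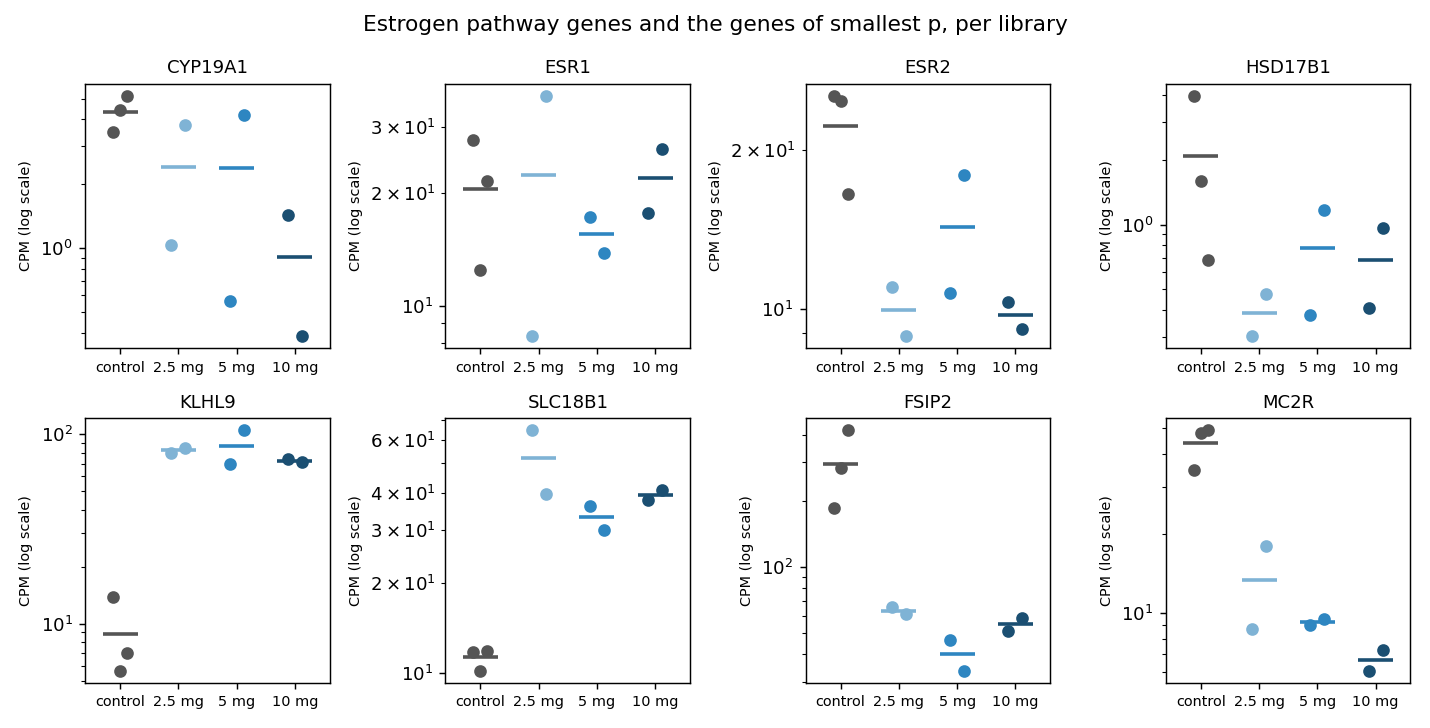
CPM on a log scale of 4 estrogen pathway genes (CYP19A1, ESR1, ESR2, HSD17B1) and of 4 of the 10 genes of smallest p, by group; each point is 1 library and each line a group mean. KLHL9 lies between 69.5 and 105 CPM in the treated libraries and between 5.64 and 13.8 in the controls, while the arms overlap for CYP19A1, ESR1, ESR2 and HSD17B1.

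**Figure D4:**
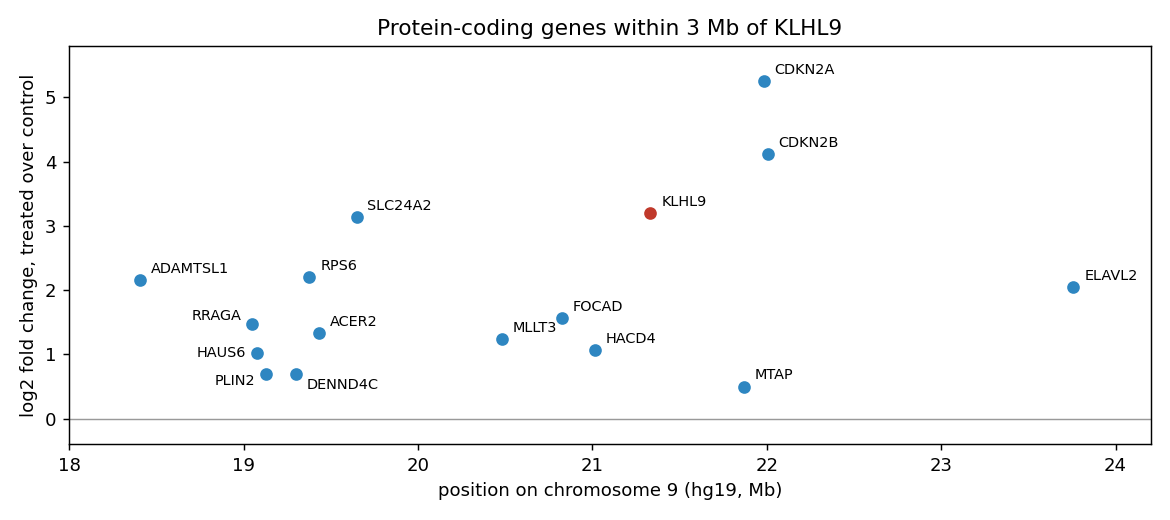
Log2 fold change, treated over control, of KLHL9 (red) and of the 15 measured protein-coding genes within 3 Mb (blue), by gene midpoint on chromosome 9 (hg19). All 15 lie above 0, from 0.496 (MTAP) to 5.25 (CDKN2A).

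Each dose was also set against the same 3 controls. At 10 mg, RNU11, the U11 RNA of the minor spliceosome, fell by 5.51 on the log2 scale (SE 0.42, edgeR adjusted p = 0.0137), from 50.3 CPM ± 9.19 (SD, n = 3) in controls; it was the 1 gene of 20807 past the threshold. All snRNA moved with it: its share was 0.0585% ± 0.0199 (SD, n = 2) at 10 mg and 0.654% ± 0.251 (SD, n = 3) in controls. The RNU11 call was lost without control replicate 1 (adjusted p = 0.0584), 2 (0.0935) or 3 (0.06), and with limma-voom (0.0717) and with only the 5 samples compared (0.0724). It was also lost without 10 mg replicate 1, in a fit that leaves a lone 10 mg library (log2 fold change -5.42). Over all alternatives its adjusted p ran from 2.19e-34 to 0.245, while its log2 fold change stayed between -5.65 and -5.33. MKI67 was lower at 10 mg without passing (log2 fold change -2.18 ± 0.48 SE, adjusted p = 0.149), and CYP19A1 had a log2 fold change of -2.25 ± 1.00 SE (adjusted p = 0.22).

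At 2.5 mg and 5 mg 0 of 20807 genes passed with edgeR; 3857 and 3720 had an unadjusted p under 0.05, DESeq2 called 1411 and 1396, and limma-voom 0 at both doses. The genes of smallest p at 2.5 mg were KLHL9 (log2 fold change 3.23 ± 0.42 SE) and SLC18B1 (2.21 ± 0.31 SE) on the higher side, and IGSF9B (-2.77 ± 0.41 SE) and TMEM72 (-3.32 ± 0.51 SE) on the lower, each with adjusted p = 0.172. IGSF9B codes for a synaptic adhesion protein. The 2.5 mg count was 189 without 2.5 mg replicate 2, with KLHL9 (adjusted p = 0.0381) and SLC18B1 (0.0225) among them, and 1 without 2.5 mg replicate 1, each a fit that leaves a lone library and assumes that it varies like the other groups. At 5 mg, RELN, which codes for the secreted guidance protein reelin (4.43 ± 0.55 SE), and KLHL9 (3.32 ± 0.42 SE) were higher, and NFIA-AS1 (-2.69 ± 0.39 SE) and FSIP2 (-2.87 ± 0.42 SE) lower, each with adjusted p = 0.185. NFIA-AS1 is antisense to NFIA, and without a stated strand setting their reads cannot be told apart. With only the 5 samples compared, 50 genes passed at 5 mg, RELN among them (adjusted p = 0.0246, within a range of 3.85e-10 to 0.464 over all alternatives). At 10 mg, 4870 genes had an unadjusted p under 0.05, DESeq2 called 2430 and limma-voom 0; the count was 54 without 10 mg replicate 2, 3 without 10 mg replicate 1 and 0 without any control library.

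Within the 6 treated tumors, the trend with dose asked which genes change as the dose doubles. Proliferation genes fell with dose as a group: 42 of 42 measured members had a negative slope, 40 of them adjusted over the list alone and 0 adjusted over all genes, with a median of 2.50-fold lower per doubling, or 6.23-fold over the 2 doublings from 2.5 to 10 mg. Relative to the control mean, the list's score was 0.857 ± 0.856 (SD, n = 2) at 2.5 mg, -0.133 ± 0.968 at 5 mg and -1.81 ± 0.379 at 10 mg, while the controls had an SD of 0.117. NUSAP1, KIF20A and TPX2, which build the mitotic spindle, had slopes of -1.84 ± 0.30, -1.84 ± 0.35 and -1.86 ± 0.37 (log2 per doubling, SE). The list passed the set test (camera adjusted p = 2.58e-35; adjusted p = 0.82 with an estimated correlation), without each library in turn and without 5 mg and 10 mg replicate 1 together; fry did not call it (adjusted p = 0.257). Replication-dependent histones (24 of 24 lower, adjusted p = 1.3e-11), ribosomal proteins (58 of 58 lower, adjusted p = 4.3e-15) and DNA repair genes such as BRCA1, EXO1 and CHEK1 (32 of 35 lower, adjusted p = 5.63e-11) fell as groups too. So did extracellular matrix genes (34 of 38 lower, adjusted p = 0.000397). Adjusted over the list alone, 0 members of these 4 lists passed, and each had adjusted p = 0.82 with an estimated correlation. Without 2.5 mg replicate 1 the ribosomal slope was -0.10 per doubling instead of -0.54, and without 2.5 mg replicate 2 the matrix list did not pass (slope 0.07, adjusted p = 0.742), nor without 5 mg and 10 mg replicate 1 together (slope -0.37, adjusted p = 0.0757).

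Lists of brain cell markers rose with dose as groups. Neuron markers rose in 28 of 28 genes (median 2.87-fold per doubling, camera adjusted p = 1.46e-08) and oligodendrocyte markers in 21 of 21 (3.06-fold, adjusted p = 9.52e-05). Astrocyte markers rose in 14 of 16 (1.59-fold, adjusted p = 0.000226). Microglia and macrophages (29 of 33, adjusted p = 0.000518), T and NK cells (21 of 25, adjusted p = 0.0124), neutrophils (9 of 13, adjusted p = 0.0377) and red blood cells (7 of 9, adjusted p = 0.0377) also rose. Each of these 7 had adjusted p = 0.82 with an estimated correlation. Antigen presentation rose in 24 of 26 genes (adjusted p = 0.0239; adjusted p = 0.87 with an estimated correlation). Adjusted over the list alone, 0 members of these 8 lists passed. CLDN11, a myelin tight junction protein, had a slope of 2.08 ± 0.45 and AGT, angiotensinogen, which astrocytes make, 0.76 ± 0.33 (log2 per doubling, SE). Of the 16 measured astrocyte genes, 5 are also in another list. AGT is also in the list for the classical and astrocyte-like glioma state, so its cell of origin is not shown. Oligodendrocytes did not pass without 10 mg replicate 1 (adjusted p = 0.0959), nor without it and 5 mg replicate 1 together (0.35), and their mean slope ran from 0.68 to 3.25 without single libraries. Microglia and antigen presentation did not pass without 2.5 mg replicate 1 or 10 mg replicate 2 (highest adjusted p = 0.452 and 0.19), nor T and NK cells without 10 mg replicate 2 (0.827). Neutrophils and red blood cells did not pass without 5 mg and 10 mg replicate 1 together (adjusted p = 0.984 and 0.49). Neutrophils were lost without 2.5 mg replicate 1, either 5 mg replicate or 10 mg replicate 1 (highest 0.871), and red blood cells without 2.5 mg replicate 1, 5 mg replicate 2 or 10 mg replicate 1 (highest 0.404).

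No gene passed for the trend with edgeR (0 of 19459, smallest adjusted p 0.676). At unadjusted p under 0.05 there were 1403, 495 rising and 908 falling; DESeq2 called 268 and limma-voom 0. PTGDS, the brain prostaglandin D2 synthase (slope 2.80 ± 0.34 SE), and ENPP6, of new oligodendrocytes (1.34 ± 0.19 SE), had the smallest p on the rising side, and DIAPH3 (-1.53 ± 0.20 SE) and CENPK, of the kinetochore (-1.53 ± 0.21 SE), on the falling side, each with adjusted p = 0.676. On simulated counts of this design the trend test called 0 genes at any fold up to 16 from the lowest to the highest dose. A count of 0 therefore carries little information.

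A test of any difference among the 3 doses called 0 of 20807 genes with edgeR (smallest adjusted p 0.244), 2690 at unadjusted p under 0.05, 1154 with DESeq2 and 0 with limma-voom. The 4 genes of smallest p were RNU11 (adjusted p = 0.244), APOD, a lipid carrier of glia, LINGO1, a brake on myelination, and GRM4, a glutamate receptor (each 0.301). APOD averaged 213 CPM ± 228 (SD, n = 6) over the treated libraries, a spread wider than its mean, and 22.1 ± 5.91 (SD, n = 3) in controls. Without 2.5 mg replicate 2, 35 genes passed, RNU11 among them, in a fit that leaves a lone 2.5 mg library and assumes that it varies like the other groups (adjusted p = 0.0354, within a range of 7.72e-16 to 0.551 over all alternatives). The count was 1 without 2.5 mg replicate 1 and 3 without 10 mg replicate 1.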

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

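The differences with dose were tested by plan; the test of the proliferation slope without 2 libraries was chosen after the result was seen.

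A library far from the others of its arm was found in 3 of 71 measures tested over the 6 treated libraries, where chance gives about 1 in 20. The ribosomal protein score was 2.44 in 2.5 mg replicate 1 and 0.433 to 0.773 in the others. ESR2 was at 17.9 CPM in 5 mg replicate 2 and 8.88 to 11 in the others. MGMT was at 1.26 CPM in 2.5 mg replicate 2 and 4.81 to 7.64 in the others.

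Reads on gene IDs without a match in the reference, which entered no comparison, took 1.61% of counts in 5 mg replicate 1 and 0.924% in 10 mg replicate 1, above the highest control (0.453%). Most fell on Entrez ID 1038, at 13310 and 7003 CPM in these libraries and at most 2344 in a control. Its name was not looked up elsewhere, and no explanation was tested.

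Within the treated libraries, 13 gene lists differed with dose by the set test of the slope, 0 of them with an estimated correlation. With fry 0 passed, and 7 of the 13 lost the call in some fits without a single library. The slope uses no control library, so it measures differences among treated libraries by dose label and not an effect of treatment. The mean log2 slope per doubling of dose was -1.32 for proliferation, -0.968 for histones, -0.763 for extracellular matrix, -0.543 for ribosomal proteins and -0.507 for DNA repair. It was 1.5 for oligodendrocytes, 1.47 for neurons, 0.747 for astrocytes, 0.6 for microglia and macrophages, 0.59 for red blood cells, 0.412 for neutrophils, 0.386 for antigen presentation and 0.352 for T and NK cells.

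Proliferation genes were lower at higher dose while markers of brain cells were higher. Admixed brain tissue in 5 mg replicate 1 and 10 mg replicate 1, the libraries with the highest neuron scores, may dilute tumor cells; without both, the mean slope was -1.11, against -1.32 with all 6 libraries, so these 2 libraries are not the whole cause. Admixture as such stays open, since without them the slope was still 1.05 for neurons (adjusted p = 2.48e-08) and 0.63 for astrocytes (0.000205), and 10 mg replicate 2 had a proliferation score of -1.55 and a neuron score of 1.66. The neuron list holds 2 of its 28 measured genes in common with other lists, and its most abundant genes MAP2 and MEG3 are as high in controls (1160 and 811 CPM) as in treated libraries (1030 and 631), while SNAP25 averaged 34.3 CPM in controls and 321 in treated. An effect of dose on dividing cells, tumor grade and the site of sampling stay open as well, untested, with 2 libraries per dose.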

How the results depend on the processing

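Scaling by DESeq2 size factors, and for genes both other filters, for lists no filter, changed no count by over 1.5 times. DESeq2 called 3185 genes for treated against control, 1411 at 2.5 mg, 1396 at 5 mg, 2430 at 10 mg, 268 for the trend and 1154 among doses, where edgeR called 0 or 1; on simulated counts it made many false calls. For treated against control, limma-voom called 1 gene, the 4-group model 1, protein-coding genes alone 2 and the fit without 5 mg and 10 mg replicate 1 together 1, and leaving out single libraries gave 0 to 22 (22 without control replicate 1). At 2.5 mg the range was 0 to 189 and among doses 0 to 35; at 5 mg it was 0 throughout, but only the 5 samples compared gave 50. At 10 mg the single call became 0 with limma-voom, and with only the 5 samples compared, and was 0 to 54 without single libraries. Fits of protein-coding genes alone and without the 2 libraries together were chosen after seeing the data; the first leaves RNU11, an snRNA, out by construction (0 calls at 10 mg), and it lowered the median of protein-coding genes from 0.24 to 0.14. Fitted with the estimated correlation, 0 of the 12 lists and 0 of the 13 trend lists passed, and with fry 1 and 0; without single libraries 8 to 13 and 11 to 16 passed. Correlations of deviations between same-numbered libraries ran from -0.198 to 0.304, with 6 of 12 over 0.1. With 2 libraries per dose, the deviations of a dose mirror each other. These correlations therefore cannot show whether same-numbered libraries pair. With the replicate block the 10 mg count was 0, and no other count of genes changed. For treatment 8 lists passed (lost: endothelial cells, camera adjusted p = 0.09, hypoxia 0.231, extracellular matrix 0.196 and p53 targets 0.149). For the trend 12 passed (lost: neutrophils, 0.0589).

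Where a direction reversed, the cause was not tested, nor for the changed counts beyond the fewer genes or libraries fitted. ESR1 ranged from -0.299 to 0.281 without single libraries and was 0.0438 without the 2 libraries together; GPER1 ranged from -0.394 to 0.115. MKI67 ranged from -0.43 to 0.2 and was 0.221 without the 2 libraries. BRCA2 ranged from -0.631 to 0.402 and was -0.337 with limma-voom, -0.283 in the 4-group model and -0.0675 with protein-coding genes alone. In the trend, GNLY ranged from -3.34 to 0.0717 and MMP9 from -3.03 to 0.38, and HBA1, 1.04 with all 6 libraries, was -0.0578 without the 2 libraries together and 0.523 to 1.56 without single ones. List slopes ranged from -0.197 to 0.902 for antigen presentation, -1.64 to 0.068 for extracellular matrix, -0.0984 to 0.63 for T and NK cells and -0.0896 to 1.08 for neutrophils, whose slope was -0.00836 without the 2 libraries together. Of 3058 alternative values of named genes and lists, 2830 kept direction and side of the threshold, 98 lost the call, 106 gained it (94 with DESeq2) and 24 reversed. That total says little about the calls, since 2697 were gene values and RNU11 at 10 mg was the 1 gene called at first. RNU11 lost its call in 7 alternatives. Of 361 values of lists that had passed, 266 kept the call, 91 lost it and 4 reversed. Depth of 9 to 18.6 M reads leaves genes near 1 CPM at few reads.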

Other observations

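The counts over other splits, the test of GC content and length and the tests of neighboring genes were planned before their results were seen; the tests on abundant lncRNA and on snRNA were chosen after.

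Among immune lists that did not pass for treated against control, single members differed. TIGIT, a checkpoint receptor of T and NK cells, averaged 3.17 CPM ± 1.85 (SD, n = 6) in treated and 12.4 ± 4.41 (SD, n = 3) in control libraries and was the 1 member of its list to pass adjusted over the list alone. POU2AF1, a B cell coactivator, averaged 31.0 CPM ± 7.70 against 57.8 ± 7.19, also the 1 of its list. Red blood cell genes went both ways (5 of 10 higher; fry for either direction, adjusted p = 0.0074; adjusted over the list alone 1 higher and 2 lower), with the band 3 gene SLC4A1 1.77-fold lower. Glioma state lists did not pass for treatment (camera adjusted p = 0.66 mesenchymal, 0.815 proneural, 0.456 classical) or for the trend (0.736, 0.134 and 0.736, with 1 proneural gene rising adjusted over the list alone). The classical list's trend had a mean slope of 0.117 and a median of -0.103, and the proneural list for treatment a mean of -0.183 with 18 of 28 genes higher in the fit.

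Other lists that did not pass for treatment were proliferation (0.332, 23 of 42 higher in the fit although the mean on the log2 CPM scale was -0.36), DNA repair (0.567, called higher with a mean of -0.03), histones (0.0631), astrocytes (0.0631), antigen presentation (0.195), neutrophils (0.2), B and plasma cells (0.367, mean -0.40 with 6 of 9 higher in the fit), T and NK cells (0.412, mean -0.08 with 14 of 25 higher), inflammatory cytokines (0.567, mean -0.17 with 17 of 30 higher), red blood cells (0.962), immediate early and heat shock genes (0.962, called higher with a mean of -0.07) and choroid plexus and ependyma (0.962), all camera adjusted p. For the trend these were oxidative phosphorylation (0.736), cholesterol synthesis (0.477), estrogen synthesis (0.0947), estrogen-responsive genes (0.443), choroid plexus (0.0947), endothelial cells (0.0993), interferon response (0.203), pericytes (0.341), B and plasma cells (0.349), p53 targets (0.439), hypoxia (0.712), cytokines (0.917) and immediate early genes (0.973, called lower with a mean of 0.01).

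For 10 mg against control, 4 genes were chosen after their values were seen, and none passed. PTGDS had a log2 fold change of 5.70 ± 0.72 SE, APOD of 4.39 ± 0.49, GSN of 3.34 ± 0.42 and APOE of 2.14 ± 0.32 (edgeR adjusted p = 0.138 for APOD and 0.149 for the others). Without 10 mg replicate 2, APOD (adjusted p = 0.0366), GSN (0.0316) and, at the threshold itself, PTGDS (0.05) passed, in a fit that leaves a lone 10 mg library and assumes that it varies like the other groups; over all alternatives the adjusted p of APOD ran from 3.51e-14 to 0.382 and of GSN from 2.51e-10 to 0.382. GSN and APOE were not particular to this dose: at 2.5 mg they averaged 252 and 180 CPM. NEAT1, an abundant nuclear lncRNA, averaged 7450 CPM ± 7110 (SD, n = 6) in treated and 16000 ± 5170 (SD, n = 3) in control libraries (adjusted p = 0.396).

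The 84 ways to split the libraries 6 against 3 give a chance level for some of the counts. For the 4930 genes at unadjusted p under 0.05, 1 of 84 splits, the real one, gave as many, but the highest other gave 4431, so other groupings of these libraries come close. For the count past adjusted p 0.05 the real value was 0, which 84 of 84 splits must reach, so this comparison says nothing about chance. The highest other gave 573. For the 12 lists, 68 of 84 splits gave as many (highest other 20), so chance is not excluded.

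Non-coding RNA was lower in treated libraries. The difference was spread over many genes, 1004 of 2804 lncRNA genes being lower and 32 higher at unadjusted p under 0.05. Without the 10 most abundant lncRNA genes the median difference from protein-coding genes was -0.884, but leaving out so few cannot move a median, so that test is void. The check of GC content and length had a value for only 79.7% of lncRNA genes, under the coverage set as its minimum. Over those 2234 genes, the difference was -0.88 before and -0.89 after removing the trend fitted on protein-coding genes. The bootstrap interval, -0.92 to -0.86, resampled genes and holds no spread between libraries. Among protein-coding genes, fold changes hardly followed GC content (Spearman -0.105) or transcript length (0.0295), so little could be removed. For the genes covered, these values argue only against a bias with GC content and length like that among protein-coding genes. The other lncRNA genes were not checked. A candidate explanation that stays open is carry-over of nuclear and non-polyadenylated RNA that differs between libraries, since snRNA genes, which carry no poly-A tail, differed from protein-coding genes by -2.23 (all 7 lower). Other classes did not decide it. Replication-dependent histones, whose messages also lack the tail, were higher in 22 of 24 cases (median 1.39-fold). That list did not pass (camera adjusted p = 0.0631), and its scores overlapped between the arms (exact permutation test, two-sided, p = 0.619). The share of small nucleolar RNA also overlapped (0.112% against 0.177%, exact permutation test, p = 0.262). Yet over 259 small nucleolar RNA genes the median log2 fold change was -0.74, with 51 lower and 3 higher at unadjusted p under 0.05. An effect of treatment stays open too, since RNA preparation and treatment are not separated by the labels.

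Some of the strongest differences may reflect tumor genomes instead of treatment, a hypothesis tested on neighboring genes. Around KLHL9, the 15 protein-coding genes within 3 Mb had a median log2 fold change of 1.47 (above 99.9% of windows with as many genes), all above 0. CDKN2A was at 5.25 and CDKN2B at 4.12, as a segment lost in more of the control than of the treated tumors could give. MTAP, which lies between KLHL9 and CDKN2A, differed least of the 15 (0.496), and a loss of the whole segment leaves this unexplained. Around EGFR, which was lower in treated libraries (-3.85 ± 1.16 SE, adjusted p = 0.108; -4.94 to -3.06 over the alternatives, adjusted p 0.0084 to 0.38) with overlapping arms (22.2 to 1300 CPM against 767 to 8020), the median was -0.601 (percentile 1.25, bootstrap interval -1.08 to -0.092). Of its 14 neighbors, 3 were above 0, and the values ran from 0.326 (CHCHD2) to -3.12 (LANCL2), as a segment amplified in more control tumors could give. Copy number was not measured here, and a treatment effect on these regions was not tested apart from it.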
